A study of Mus musculus with 6 samples.

How the data were processed

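RNA of whole aortas was sequenced from 6 libraries, 3 from Apoe-/- mice given Apoe-/- bone marrow (control recipients) and 3 from Apoe-/- mice given Apoe-/-Sept2C111A bone marrow (Sept2C111A recipients). All mice had been infused with angiotensin II for 28 days. Per the labels' protocols, RNA was extracted with TRIzol and messenger RNA was captured on oligo(dT) beads, so transcripts without a poly(A) tail are under-represented. The deposited values are expected counts per gene, one file per library, as estimated by the authors' counting program and not normalised. The submitters' processing notes name Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the genome build mm10. The Bowtie2 version, the gene annotation, read filters and the strand setting are not given in the sources used here.

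RSEM divides reads that match several transcripts or genes among them by their estimated abundance, which gives fractional values. Between 34.6% and 35.9% of the values in each library were fractional. Genes with near-identical copies (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Ly6c2, the Cd209 and Sirpb1 families) therefore hold divided reads, and their single values are uncertain. Without a stated strand setting, reads of overlapping antisense genes cannot be separated either. Because the files hold counts of whole tissue, a level reflects both the cell types present and the expression in each of them, and a transcript made by abundant cells of a library lowers the share left to other transcripts.

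The files held 18749 gene rows, of which 262 had no read in any library. Gene names had passed through a spreadsheet: 12 septin rows and 13 rows of the March or Marc families were stored as dates. The septin dates were turned back into septin names, since each number occurred once, while the other dates were kept and 2 of them, each on a pair of rows, were told apart by row only. A total of 17993 names were found in the GENCODE vM21 annotation of the same genome build, which supplied all coordinates (1-based). In 1 file of the Sept2C111A group the column heading carried another library number than the file was deposited under, and the sample recorded by GEO was used.

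Library totals ran from 17082719 to 20494928 expected counts, with 16690 to 17049 genes detected per library. A gene at 1 CPM is thus covered by about 20 reads per library, and the spread between animals, not counting error, sets the precision of most values below. Counts between replicates of a group differed far beyond sampling noise, with chi-square values per degree of freedom from 50.2 to 237. No library was thus a duplicate of another of its group. The design text gives 3 mice per group, and nothing else in the labels says how the samples were collected or batched.

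Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10, which left 14466, and libraries were scaled by TMM. The main test was edgeR's two-sided quasi-likelihood F test with group as the single factor, and Benjamini-Hochberg adjusted p under 0.05 counted as passing. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over 3 libraries. Log2 fold changes are Sept2C111A recipients minus control recipients, and their SE was derived from the fold change and its F value. DESeq2 1.42.0 with default settings was run as another test, chosen before the data were examined, and its calls are reported beside those of edgeR. An adjusted p that DESeq2 withheld was left missing.

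Before the data were examined, 29 gene lists with 672 entries were fixed, covering cell types of the aortic wall and its surroundings, blood cells, septins, Rac and nitric oxide signalling, matrix, stress and metabolism. A total of 663 entries had a row. Lists with at least 5 tested members, 28 of them, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data and with fry. Genes named in the text follow a rule fixed at the same time. It takes Septin2, Apoe, Tiam1, Rac1 and Nos2, then, since fewer than 5 genes passed, the 10 genes of smallest p in each direction with a mean count of at least 50, and the 3 members of smallest p of each list, with predicted genes skipped in the second step. Any other gene named was chosen after its values were seen.

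The tests were tried on simulated counts for the same 14466 genes in which 200 were changed. Of 50 genes changed per fold size, edgeR recovered 9 at 2-fold, 43 at 4-fold, 46 at 8-fold and 48 at 16-fold, with 13 false calls, and DESeq2 recovered 21, 47, 49 and 50, with 67 false calls. With no gene changed, edgeR made 0 calls and DESeq2 made 42. The simulation gave both groups the same dispersion for a gene and made no library an outlier. In the data, chi-square values per degree of freedom were 124 to 237 between controls and 50.2 to 116 between Sept2C111A libraries. The recovery and false-call counts therefore need not hold for these data. In the simulated lists, camera called 4 of 4 shifted lists and 1 of the others. These lists held random genes, each simulated independently. They therefore do not show how camera at the preset correlation behaves for lists whose members vary together. Alternatives covered the scaling, the low-count filter, the tool, a fold threshold, other adjusted p thresholds, 1 surrogate variable (sva 3.50.0), a replicate block, and leaving out each library.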

Results

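The data are gene counts from aortas of Apoe-/- mice, which lack apolipoprotein E and develop aortic aneurysms under angiotensin II. The mice received bone marrow that either carried an altered septin-2, Sept2C111A (by its name a cysteine exchanged for alanine), or did not, and each group held 3 libraries. The series title links the study to S-nitrosylation of septin-2 in macrophages. The comparison therefore asks how the aorta's transcripts differ when blood-derived cells carry the altered septin-2. The expected counts summed to 18472362, 18946477 and 20494928 in the libraries of control recipients and to 18677152, 18736010 and 17082719 in those of Sept2C111A recipients. Values below are mean CPM ± SD over the 3 libraries of a group.

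Aortas of Sept2C111A recipients had lower levels of the neutrophil gene list and higher levels of the clock and adventitial fibroblast lists, in list tests at a preset correlation that gave 0 calls with an estimated one. At the preset correlation, 6 of the 10 ways to split the libraries into groups of 3, the real one included, gave at least the 14 list calls of the real split. Hmox1, the enzyme that degrades haem, stood at 823 ± 394 CPM in control recipients and 42.6 ± 11.01 CPM in Sept2C111A recipients, a 19.3-fold difference. Per3, a clock gene, stood at 12.6 ± 2.5 and 31.4 ± 1.53 CPM. No single gene passed edgeR's test after adjustment over 14466 genes: 0 were higher and 0 lower, with a smallest adjusted p of 0.316. At an unadjusted p under 0.05 edgeR gave 2170 genes, 892 higher and 1278 lower, where 723 are expected by chance on average. Other splits of the 6 libraries into groups of 3 gave from 103 to 1156. DESeq2 called 145 genes higher and 425 lower at adjusted p under 0.05, of which 83 and 365 differed by at least 2-fold, and limma-voom with libraries weighted by quality called 0 (smallest adjusted p 0.263).

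The 3 libraries of one group lay wholly above those of the other for 3340 genes (23.1%). Chance gives 10% on average over all splits of the 6 libraries into groups of 3. Genes vary together, so a single split can lie far from that average, and the share in the other splits was not counted. The spread was wide among control recipients: the first 2 principal components held 46.6% and 28.1% of the variance, and controls 1 and 3 lay far from the other 4 libraries. The DESeq2 total of 570 genes depended on single libraries. It was 330 without control 1, 1767 without control 2 and 345 without control 3. Without Sept2C111A libraries 1, 2 and 3 in turn it was 241, 640 and 116. A total of 83 of the 570 genes were called in each of the 6 fits that left out a library, 9 higher and 74 lower. With controls 1 and 3 both left out, DESeq2 called 5 genes higher and 23 lower, but that fit sets 1 control library against 3 and takes its spread from the Sept2C111A libraries alone, so it is no test of stability.

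Septin2 itself (chromosome 1, 93478964 to 93510260, mm10), the gene altered in the donor marrow, was at 313 ± 23.3 CPM in control recipients and 309.8 ± 35.8 CPM in Sept2C111A recipients, a log2 fold change of -0.02 (SE 0.16). Counts per gene cannot show an exchanged amino acid, and cells other than those of marrow origin also contribute, so this level does not check the genotype. Apoe (chromosome 7, 19696109 to 19699188) is disrupted in all mice, and its residual counts ran from 171 to 268 in control recipients and from 246 to 532 in Sept2C111A recipients, with a log2 fold change of 0.80 (SE 0.32, edgeR adjusted p = 0.331). Tiam1 (chromosome 16, 89787111 to 90143769), an exchange factor that activates Rac1, was at 33.9 ± 13.7 and 34.0 ± 15.99 CPM. Rac1 (chromosome 5, 143503634 to 143528036) was at 336 ± 34.1 and 288 ± 11.7 CPM, a log2 fold change of -0.22 (SE 0.15, edgeR adjusted p = 0.471). Nos2 (chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase, was at 3.08 ± 1.77 and 1.79 ± 1.29 CPM, with an edgeR adjusted p of 0.541.

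Among genes lower in Sept2C111A recipients, those of smallest p included several known from myeloid cells. Hmox1 (chromosome 8, 75093621 to 75100589) had a log2 fold change of -4.27 (SE 0.47) and a DESeq2 adjusted p of 2.44e-19, and its level in each control, from 413 to 1198 CPM, exceeded the highest Sept2C111A library at 54.9 CPM. Siglecf (chromosome 7, 43351341 to 43359531), a lectin of eosinophils and some macrophages, was at 6.86 ± 4.02 and 0.145 ± 0.029 CPM. Clec4n (chromosome 6, 123229843 to 123247021), the fungal-sensing receptor dectin-2 of myeloid cells, was at 96.4 ± 42.3 and 13.02 ± 4.70 CPM, a log2 fold change of -2.89 (SE 0.44). Ms4a6d, a membrane protein of macrophages, was at 82.1 ± 21.6 and 27.0 ± 4.42 CPM. Pf4, the platelet chemokine that macrophages also make, was at 102 ± 26.3 and 34.3 ± 6.01 CPM. Sphk1, a sphingosine kinase, was at 43.4 ± 4.36 and 16.9 ± 4.05 CPM. Treml4, Sh2d5, Rab15 and Inava completed the group, with log2 fold changes of -3.52, -4.21, -2.97 and -5.48, and stood at under 2 CPM in every Sept2C111A library.

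Among genes higher in Sept2C111A recipients, Dbp (chromosome 7, 45705088 to 45710203), a transcription factor driven directly by the clock, had the largest fold change of the 10 genes of smallest p, at 9.78 ± 6.01 and 49.9 ± 11.6 CPM, a log2 fold change of 2.35 (SE 0.45). Per3 (chromosome 4, 151003652 to 151044665) had a log2 fold change of 1.32 (SE 0.18) and a DESeq2 adjusted p of 1.02e-06. C1qtnf7, a secreted C1q-like protein, was at 21.4 ± 5.21 and 59.6 ± 5.07 CPM, and Igfbp6, which binds insulin-like growth factor 2, at 77.0 ± 13.3 and 163 ± 14.2 CPM. Gabra3, a receptor subunit for GABA, was at 68.4 ± 14.3 and 141 ± 15.9 CPM. Rgs7bp, Selenbp1, Tmem158, Gstt1 and Tent5a had log2 fold changes of 1.51, 1.12, 1.06, 0.91 and 0.72. All 20 genes named in these 2 paragraphs had separate groups and a DESeq2 call, none had an edgeR adjusted p below 0.316, and 18 were called by DESeq2 in each of the 6 fits that left out a library, the exceptions being Gabra3 and Selenbp1. The genes were chosen by smallest p in these same libraries, which favours separate groups and DESeq2 calls. These counts are therefore no independent sign of stability.

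**Figure D1:**
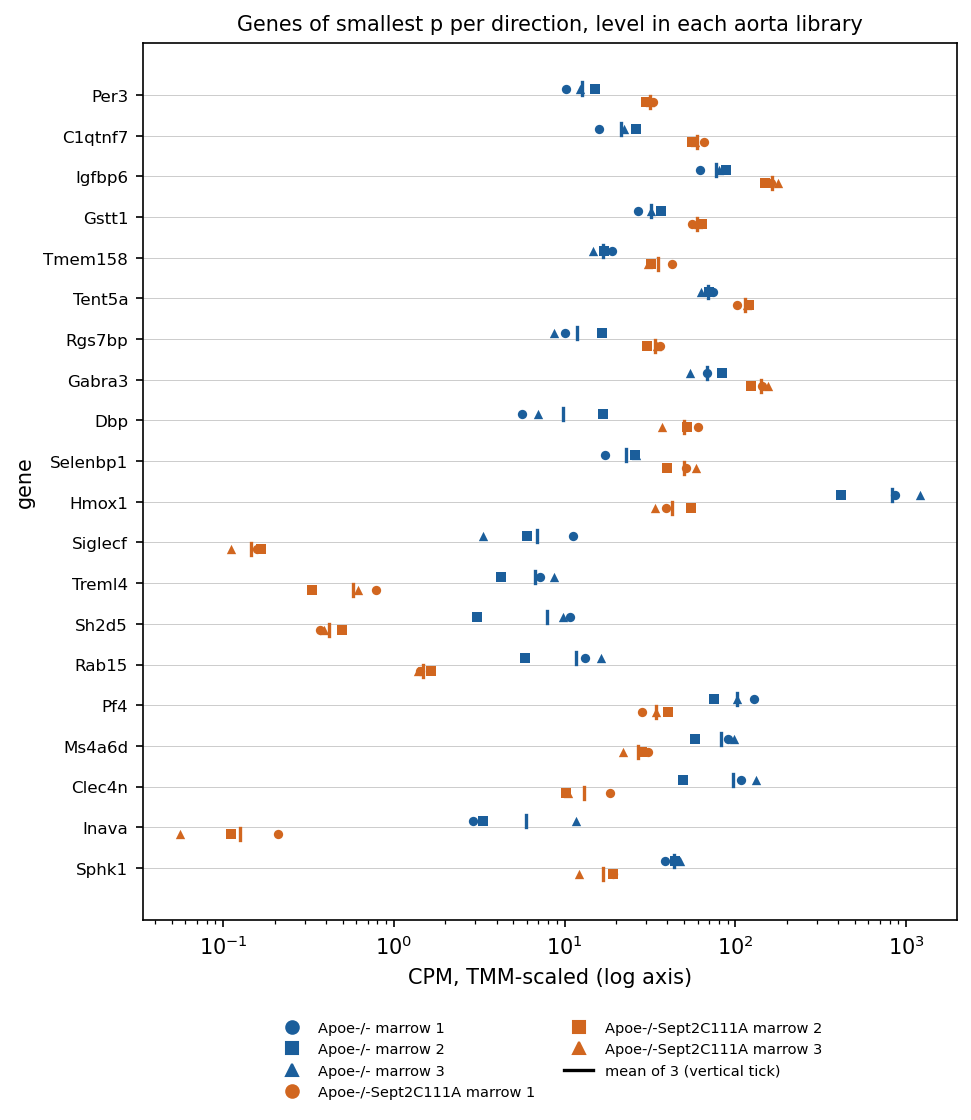
Level of the 20 genes of smallest p in each library, in CPM on a log axis, with 1 point per library, blue for control recipients and orange for Sept2C111A recipients, and a vertical tick at each group's mean. The 3 Sept2C111A libraries lie to one side of the 3 controls for all 20 genes, which their choice by smallest p favours. Hmox1 spans 413 to 1198 CPM in controls against 33.7 to 54.9 CPM.

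Neutrophil genes were the list with the largest median difference. All 12 tested members were lower in Sept2C111A recipients, with a median log2 fold change of -4.44, and 11 passed when adjusted over the list alone, 0 over all genes, and 9 by DESeq2. S100a8 and S100a9, the calprotectin subunits that fill the neutrophil cytoplasm, were at 256 ± 345 and 241 ± 340 CPM in control recipients against 1.8 ± 1.1 and 2.3 ± 0.6 CPM. Retnlg, a resistin-like protein of neutrophils, was at 13.7 ± 16.99 and 0.3 ± 0.1 CPM. The list was lower by camera (adjusted p = 6.66e-08), with adjusted p = 0.602 with an estimated correlation. Control 1 was richest in these genes, at a mean log2 level 4.14 above their average over the 6 libraries, against 1.29 in control 3 and -0.33 in control 2, while the Sept2C111A libraries lay at -1.54, -1.92 and -1.64. Without control 1 the median log2 fold change was -2.53, that of S100a9 was -4.28 in place of -6.70, and that of Retnlg was -3.57 in place of -5.36. Globin and other erythroid genes, which mark blood in the sample, were at 1.74, -2.09 and 1.17 in controls 1, 2 and 3 and at 0.79, -0.81 and -0.80 in the Sept2C111A libraries on the same scale, and their list did not pass (adjusted p = 0.257), although all 6 tested members were lower, with a median log2 fold change of -1.22. The erythroid median was -0.22 without control 1, -2.12 without Sept2C111A library 1 and -0.80 without Sept2C111A library 3, and the list passed as lower without control 2 (adjusted p = 0.00803 by camera) and without Sept2C111A library 1 (adjusted p = 0.0252).

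Inflammatory cytokines, chemokines and NF-kB targets were lower as a list (adjusted p = 9.07e-06 by camera, adjusted p = 0.602 with an estimated correlation), with 30 of 36 tested members lower, 6 called by DESeq2 and 0 adjusted over the list alone. Cxcl5 and Cxcl2, chemokines that draw neutrophils, had log2 fold changes of -6.32 (SE 1.22) and -6.39 (SE 1.68), and Lif, a cytokine of the interleukin-6 family, -2.51 (SE 0.63). The list's median of -0.91 became -0.32 without control 1, where its level was 1.65 above average, and control 2, at -0.36, was level with Sept2C111A library 1 at -0.36. Without control 1 the log2 fold change of Cxcl2 was -3.39. Monocyte and macrophage markers were lower as a list too (adjusted p = 5.04e-05 by camera, adjusted p = 0.602 with an estimated correlation), with 26 of 30 members lower and a median of -0.77, or -0.50 without control 3. The groups overlapped in the level of this list, with control 2 at 0.05 and Sept2C111A library 1 at 0.06. The 5 members DESeq2 called were Clec4d, Cd300lb, Tyrobp, Fcer1g and Itgam, receptors, adaptors and an integrin that neutrophils also carry, and 0 members passed when adjusted over the list alone. Clec4d was at log2 fold change -4.53, and at -3.23 without control 1. B cell and plasma cell genes were lower as a list (adjusted p = 8.41e-07 by camera, adjusted p = 0.602 with an estimated correlation), 15 of 17 members lower, with 2 adjusted over the list alone, Fcmr, an IgM receptor, at 1.2 ± 0.3 and 0.1 ± 0.0 CPM, and Cr2, complement receptor 2. DESeq2 called both with all libraries, and with 1 library left out it called Fcmr in 6 of 6 fits and Cr2 in 0. The list's call was lost when genes under a mean count of 50 were removed, and its median of -1.53 was -0.87 without control 1. In level, control 2 at 0.07 lay below Sept2C111A library 1 at 0.29.

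Rac GTPases, their exchange factors and the phagocyte NADPH oxidase were lower as a list (adjusted p = 2.42e-05 by camera, adjusted p = 0.602 with an estimated correlation). Of 25 tested members 21 were lower, 5 were called by DESeq2 and 0 passed when adjusted over the list alone. Vav1, a blood cell exchange factor for Rac, was at 61.5 ± 32.9 and 17.7 ± 6.4 CPM, Prex1, another exchange factor, had a log2 fold change of -0.91 (SE 0.24), and Ncf1, the p47phox subunit of the oxidase, of -2.47 (SE 0.68), which was -1.26 without control 1. The list's level was 0.45, 0.05 and 0.35 in controls 1, 2 and 3 and -0.12, -0.30 and -0.43 in Sept2C111A libraries 1, 2 and 3. Neutrophil genes were highest in control 1 as well. Without control 1 the Rac list's median log2 fold change was -0.45, against -0.35 with all libraries. The neutrophil list was still lower then, with a median of -2.53. Leaving out control 1 thus cannot tell a change of Rac and oxidase genes from a difference in neutrophil content. In the nitric oxide list the median log2 fold change was 0.00 and the mean -0.77, so both summaries are given, and the list did not pass (adjusted p = 0.312). When adjusted over the list alone 5 members were lower and 1 higher. Arg1, which competes with nitric oxide synthase for arginine, was at 403.5 ± 485 and 1.9 ± 0.6 CPM, a log2 fold change of -7.73 (SE 1.22, DESeq2 adjusted p = 2.48e-16). Control 1 held 959 CPM of Arg1, against 66.3 in control 2 and 185 in control 3. Gclm, which makes glutathione's precursor, and Txnrd1, a thioredoxin reductase, had log2 fold changes of -1.18 (SE 0.24) and -0.98 (SE 0.23). Septins gave no call (adjusted p = 0.557), with 8 of 11 tested members lower and log2 fold changes of Septin7 and Septin9 at 0.00 and -0.37.

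Cell cycle genes were lower as a list (adjusted p = 7.14e-13 by camera, adjusted p = 0.602 with an estimated correlation), with all 34 members lower and a median log2 fold change of -1.42, or -0.79 without control 3 and -2.14 without Sept2C111A library 2. The groups overlapped in the level of this list: controls 1, 2 and 3 were at -0.19, 0.63 and 1.44 relative to the average, and the Sept2C111A libraries at -0.84, 0.26 and -1.29. DESeq2 called 3 members, and 0 passed when adjusted over the list alone; Mcm2 and Mcm5, subunits of the replicative helicase, were at 19.1 ± 5.2 and 9.1 ± 1.4 CPM and at 21.6 ± 4.8 and 10.7 ± 3.1 CPM. Matrix genes were lower as a list (adjusted p = 4.41e-05 by camera, adjusted p = 0.699 with an estimated correlation), with 36 of 42 members lower and a median of -0.66. DESeq2 called 1 matrix gene, Thbs1, the matricellular thrombospondin-1, at 3727 ± 2564 and 327 ± 176 CPM, and 0 passed when adjusted over the list alone. The matrix median was -0.32 without control 3, -1.02 without Sept2C111A library 2 and -0.42 without Sept2C111A library 3, and control 1, at -0.26, lay below Sept2C111A library 2 at 0.25. Proteases and their inhibitors were lower as a list (adjusted p = 0.0134 by camera, adjusted p = 0.602 with an estimated correlation), with 22 of 31 tested members lower and 2 adjusted over the list alone. These were Mmp9, a gelatinase, at 472 ± 432 and 5.0 ± 3.2 CPM, and Adamts4, an aggrecanase, at 82.7 ± 33.3 and 19.6 ± 5.5 CPM, while Timp4, an inhibitor, had a log2 fold change of 1.26 (SE 0.32). The protease call was lost without control 3 and without Sept2C111A library 3, and its median of -0.37 was -0.12 without control 3. Unfolded protein response genes were lower as a list (adjusted p = 1.8e-05 by camera, adjusted p = 0.602 with an estimated correlation), with 19 of 20 lower. DESeq2 called 2 of them, the disulfide isomerases Pdia6 and Pdia4, at log2 fold changes of -0.74 (SE 0.17) and -0.71 (SE 0.17), and 0 passed when adjusted over the list alone.

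Adventitial fibroblast markers were higher as a list (adjusted p = 3.64e-07 by camera, adjusted p = 0.215 with an estimated correlation). Of 20 members 16 were higher, 8 passed when adjusted over the list alone, 0 over all genes, and 7 by DESeq2, and this was the single list that fry also called in one direction (adjusted p = 0.0439). Cd34 was at 225 ± 39.7 and 396 ± 14.7 CPM, Clec3b, which encodes tetranectin, at 76.3 ± 31.3 and 244 ± 87.6 CPM, and Vit, a matrix protein, at 18.2 ± 7.7 and 45.6 ± 4.1 CPM. Clock genes were higher as a list (adjusted p = 6.58e-05 by camera, adjusted p = 0.602 with an estimated correlation), 14 of 18 members higher, 6 when adjusted over the list alone and 5 by DESeq2. Besides Per3 and Dbp, Hlf, a transcription factor related to Dbp, was at log2 fold change 1.66 (SE 0.34). The list's median of 0.51 was 0.19 without control 3 and 0.31 without Sept2C111A library 3.

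Adipocyte genes were higher as a list (adjusted p = 1.97e-07 by camera, adjusted p = 0.602 with an estimated correlation), 23 of 24 members higher, with 0 adjusted over the list alone and 0 by DESeq2. Lpl, lipoprotein lipase, was at 418 ± 86.8 and 776 ± 267 CPM. Control 3 held the least adipocyte signal, 2.40 below the average of the 6 libraries, and the median of 1.09 was 0.71 without it. The groups overlapped, since control 1, at 0.22, lay above Sept2C111A library 2 at -0.12. Respiratory chain genes were higher as a list (adjusted p = 4.55e-07 by camera, adjusted p = 0.699 with an estimated correlation), all 34 members higher with a median of 0.49, and 0 adjusted over the list alone. Control 1, at 0.13, lay above Sept2C111A library 2 at -0.20 in their level. That median was 0.74 without control 1, 0.33 without control 3 and 0.19 without Sept2C111A library 3. Contractile genes of smooth muscle were higher as a list (adjusted p = 2.71e-04 by camera, adjusted p = 0.699 with an estimated correlation), 23 of 25 members higher, with 0 adjusted over the list alone. Control 3 was 1.22 below average for them and 1.03 above average for matrix genes. The smooth muscle call was lost without control 3, where the median of 0.58 was 0.19.

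The remaining lists did not pass with all 6 libraries. Lipid uptake and foam cell genes had an adjusted p of 0.116, but 0.0121 without control 1, 0.00427 without Sept2C111A library 1 and 0.0223 with the replicate number as a block, lower each time, with 5 members lower when adjusted over the list alone. Olr1, a receptor for oxidised low-density lipoprotein, was at 17.4 ± 12.3 and 1.6 ± 0.5 CPM, Soat1, which esterifies cholesterol, had a log2 fold change of -1.16 (SE 0.24), and Spp1, which encodes osteopontin, was at 687.5 ± 614 and 93.6 ± 22.4 CPM. Control 3 held 1390 CPM of Spp1, and its log2 fold change of -2.88 was -1.84 without that library. By camera at the preset correlation the adjusted p was 0.222 for T cells, 0.223 for lymphatic endothelium, 0.228 for striated muscle, 0.388 for interferon response, 0.453 for nerve, 0.47 for TGF-beta signalling, 0.523 for cholesterol synthesis and 0.557 for MHC class II and dendritic cells. It was 0.755 for immediate-early genes and 0.774 for endothelium, where the median of 0.01 and the mean of -0.03 differed in sign. Leaving out 1 library brought some of these lists past the threshold. Without control 1 these were cholesterol synthesis (adjusted p = 0.00687, higher), striated muscle (0.0233, higher) and lymphatic endothelium (0.0426, lower), and without control 3 endothelium (0.00312, higher, median 0.41). Without Sept2C111A library 1 they were T cells (0.00138, lower), striated muscle (0.0105, higher), lymphatic endothelium (0.0297, lower), nerve (0.0417, lower) and interferon response (0.0492, lower). Without Sept2C111A library 2 they were MHC class II (0.0174, higher) and endothelium (0.0321, higher). Mesothelial markers had 4 tested members and were not tested.

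**Figure D2:**
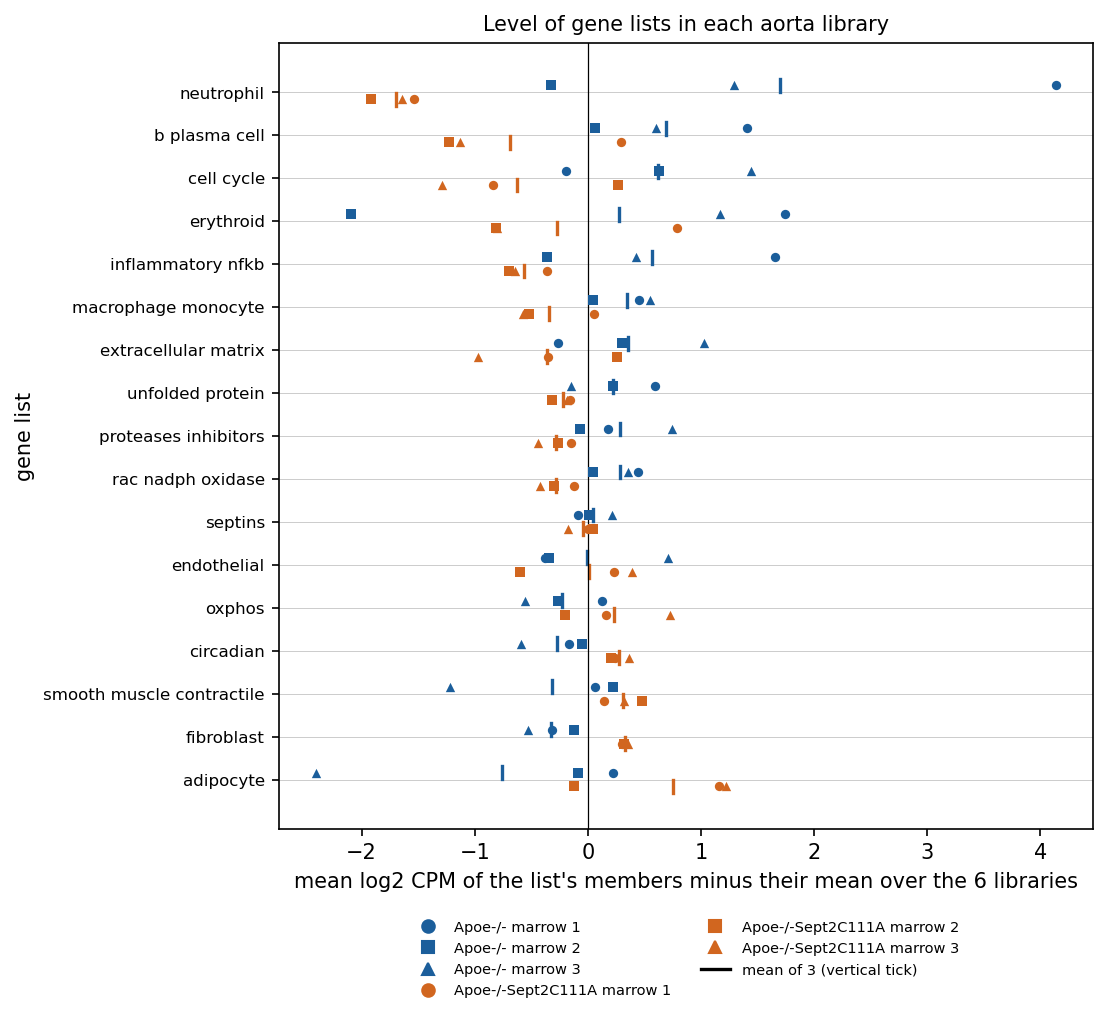
Level of 17 gene lists in each library, as the mean log2 CPM of the members minus their mean over the 6 libraries, with 1 point per library, blue for control recipients and orange for Sept2C111A recipients, and a vertical tick at each group's mean. Neutrophil genes lie at 4.14 in control 1 and between -1.92 and -1.54 in the Sept2C111A libraries, and adipocyte genes lie at -2.40 in control 3.

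The 14 list calls, 5 higher and 9 lower, were made with the preset correlation. When camera estimated the correlation from the data, which also lowers its degrees of freedom, 0 remained. The mean level of the list separated the groups in 6 of them, and overlapped in 8.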

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

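The added alternatives (robust edgeR, the newer edgeR dispersion, controls 1 and 3 left out together, and all refits of DESeq2) were chosen after seeing the data. edgeR gave 0 genes higher and 0 lower under each of its settings, with smallest adjusted p from 0.0814 to 0.683 when one library was left out (0 to 0 genes), while DESeq2 gave 145 and 425. Among lists, an estimated correlation gave 0 higher and 0 lower, and fry gave 1 and 0, where 5 and 9 had been called. The camera runs differed in the correlation setting, preset at 0.01 or estimated. Estimating it also lowers the degrees of freedom that camera uses, to the residual 4. For fibroblast markers the unadjusted camera p went from 5.21e-08 to 0.00767 although the estimate was near the preset value. The loss of calls is therefore not due to the correlation alone. The estimate was 0.88 for cell cycle, 0.92 for neutrophil and 0.94 for respiratory chain genes, but 0.023 for fibroblast markers. The preset value thus treats members of the first lists as nearly independent, which their estimates do not bear out. Why fry gave fewer calls was not tested. Leaving out controls 1 and 3 gave 9 lists higher and 8 lower. That setting holds 1 control library, which is assumed to vary like the Sept2C111A libraries, so it does not bear on stability. In it the smooth muscle, inflammatory and protease calls ended, erythroid genes passed as higher where their direction had been lower, and immediate-early, endothelial, interferon and striated muscle genes passed as higher and foam cell genes as lower. Leaving out one library gave 5 to 7 lists higher and 8 to 15 lower, with 15 lower without Sept2C111A library 1. DESeq2 gave 20 to 740 genes higher and 96 to 1027 lower when one library was left out, and 5 and 23 without controls 1 and 3, again with 1 control library. Genes shared with the 570 calls numbered 549 without control 2 and 104 without Sept2C111A library 3, all with the same sign. Genes named from the lists varied in this: S100a8, Mmp9 and Thbs1 were called in 6 of the 6 fits that left out a library. Mcm5 was called in 1 of them, and Tyrobp, Prex1, Txnrd1 and Timp4 in 2 each.

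The sample numbers were not taken to pair libraries: same-numbered libraries had correlations of 0.0055, 0.15 and -0.17 in their deviations from the group means, and only those numbered 2 matched each other best. With the replicate number as a block, edgeR gave 0 genes higher and 0 lower (smallest adjusted p 0.383), lists gave 5 and 10, and DESeq2 gave 88 and 370.

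Of 1487 values of 83 named genes under alternatives, 1421 kept their direction and side of the threshold, 53 became significant and 13 changed sign. All 53 came from DESeq2. Each of the other alternatives called 0 genes, so the side of the threshold could not change there and its constancy is no sign of stability. The sign changes were in Septin2 and Tiam1, both near 0. Septin2 was 0.014 with library size only, 0.017 with 1 surrogate variable and between -0.113 and 0.0551 without one library. Tiam1 was -0.00072 with the filter at a mean count of 50, -0.020 with the replicate block, -0.094 by limma-voom with quality weights, -0.26 with 1 surrogate variable and between -0.437 and 0.361 without one library. Depth limits genes below 1 CPM, such as Siglecf and Inava in Sept2C111A recipients, where a library holds only a few reads.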

Other observations

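The platelet, haem and iron, and resident macrophage gene groups, and the tests of explanations, were chosen after the results were seen. The 3 gene groups were for that reason not tested for enrichment, and edgeR called 0 of their members over all genes.

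Of 19 measured platelet genes, Pf4 included, DESeq2 called 10, all lower in Sept2C111A recipients. The log2 fold change was negative for all 19, with a median of -1.98, and the other 9 did not pass. Ppbp, a platelet chemokine, was at 159, 10.7 and 34.2 CPM in controls 1, 2 and 3 and at 3.36, 1.27 and 2.00 CPM in the Sept2C111A libraries. Itga2b, the platelet integrin subunit, was at 39.7, 8.78 and 21.2 CPM against 5.31, 3.76 and 5.90 CPM. Among those that did not pass, Itgb3 and Gp1ba had log2 fold changes of -0.09 (SE 0.28) and -0.07 (SE 0.25). Of 20 genes of haem, iron and glutathione handling, DESeq2 called 9, all lower, and the log2 fold change was negative for 16. Besides Hmox1, the iron exporter Slc40a1 was at 42.1, 58.7 and 192 CPM in controls 1, 2 and 3 and at 14.1, 13.2 and 12.5 CPM, and the cystine importer Slc7a11 was at 68.4, 5.73 and 26.9 CPM against 1.26, 0.72 and 1.50 CPM. Gclc and Nqo1, other genes of the same oxidative stress response, had log2 fold changes of -0.04 (SE 0.16) and 0.38 (SE 0.21).

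Of 20 genes of resident or alternatively activated macrophages, DESeq2 called 6, all higher in Sept2C111A recipients. The log2 fold change was positive for 18, but most of these did not pass, such as Mrc1 at 0.12 and Gas6 at 0.10. The mean level of the 20 genes in Sept2C111A library 2, at -0.11 relative to the 6 libraries, lay close to control 1 at -0.16. That library was the lowest of its group, as control 3 was among controls, at -0.77. Adipocyte genes were lowest in the same libraries, at -0.12 and -2.40. Whether the macrophage genes followed the amount of fat in the samples was not tested. Cd209f, a lectin of tissue macrophages, was at 6.70, 5.68 and 3.81 CPM in controls 1, 2 and 3 and at 22.7, 12.9 and 12.7 CPM in the Sept2C111A libraries. Retnla, a resistin-like protein of alternatively activated macrophages, was at 11.6, 8.15 and 3.51 CPM against 52.0, 16.4 and 50.8 CPM, and Folr2, a folate receptor, at 26.2, 27.7 and 25.3 CPM against 46.0, 39.4 and 34.7 CPM. Arg1, another gene of alternative activation, was far lower, as given above. The Cd209 genes share reads, so single values in that family are uncertain.

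The lower level of neutrophil genes is not set by control 1 alone, since without it the median log2 fold change of the list was -2.53, and controls 2 and 3 both lay above the 3 Sept2C111A libraries. More whole blood left in control aortas would raise neutrophil and erythroid genes together. The neutrophil mean minus the erythroid mean still differed by -2.85 between groups (log2), with all 3 controls above all Sept2C111A libraries. This speaks against such blood as the whole cause only if both groups' blood held neutrophils and red cells in the same ratio, which was not measured. The erythroid mean also rests on 6 genes, and the difference of 1.76 in control 2 came with a low erythroid level of -2.09. Platelet genes, another marker of blood, had a median of -1.98 and were highest in control 1, at 1.78, so blood or thrombus poor in red cells stays open. The donor genotype, a difference in aneurysm between these particular mice, and an unrecorded batch stay open too, and no label separates them. A candidate explanation is that fewer neutrophils entered the wall, which whole-tissue counts cannot tell from lower expression per cell.

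Fewer macrophages of unchanged makeup would lower the macrophage list members alike, so the members were compared with that list's median log2 fold change of -0.77. Of its 30 members, 3 lay above this median (adjusted over the list), Mrc1 (by 0.88, adjusted p = 0.0174), Lyve1 and Cd163, and 1 below it, Clec4d. With 1 library left out, from 0 to 2 members passed above it, and 0 without control 3, Sept2C111A library 2 or Sept2C111A library 3, while Mrc1 stayed above by 0.67 to 1.08. Neutrophils share 9 members, which differed by -1.57 (log2) between groups, and the other 21 differed by -0.32. This split was made after the called members were seen and holds all 5 of them on one side, so an effect of shared genes cannot be told apart from one of macrophages. The shared members also enter the median, and the median's own error was not counted. The comparison therefore does not decide whether the makeup changed. Fewer macrophages of unchanged makeup, a change in their makeup, with or without fewer of them, and the donor genotype stay open.

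In mean level, the 7 clock output genes were higher in each Sept2C111A library than in each control. Aortas taken at another phase of the day could give this, and would lower the genes of opposite phase (Arntl, Npas2, Clock, Nfil3 and Cry1). These 5 genes differed by -0.22 (log2), within the spread of 0.44 among controls, so the collection time cannot be told apart from an effect of the marrow genotype. The labels give no time of collection.

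The 6 libraries can be split into groups of 3 in 10 ways, too few to exclude chance at 0.05. edgeR gave 0 genes in the real split and at most 0 in the other splits, so 10 of 10 gave as many. At an unadjusted p under 0.05 the real split gave 2170 genes and the highest other 1156, and 1 split reached the real count. DESeq2 gave 570 genes against 251 in the highest other split, and 1 split reached the real count. For gene lists the real split gave 14 calls and the highest other 19, and 6 of the 10 splits gave at least 14.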
